A study of Mus musculus with 6 samples.

How the data were processed

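The samples were 6 RNA sequencing libraries of total RNA from mouse cerebral cortex at postnatal day 8, 3 from control (Pen-2 F/F) and 3 from Pen-2 cKO (Pen-2 F/F with hGFAP-Cre) mice. Libraries were made with the VAHTS Universal V6 kit, per the labels' protocols, which do not state whether ribosomal RNA was removed or poly(A) RNA selected. The genome build was mm10, per the submitters' processing notes. The aligner, the counting program, the annotation release and whether counting used strand are not given in the sources used here.

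The deposited per-library values are FPKM, fragments scaled for gene length and depth, per the file headers, although the table is named for raw counts. The values are decimals, and in single-transcript genes the lowest ones are whole multiples of a step that is the same share of 1 fragment in each library. From 659 such genes the steps implied 20251900 to 26809300 fragments per library. With that depth, 78.7% of the values of single-transcript genes came out within 0.01 fragments of a whole number, but only 3.5% in genes with several transcripts, whose effective length is not known, so counts were not recovered and no count test was run. The 6 per-library tables held values identical to the series-wide table. The authors' deposited group values are also in FPKM, and the authors' deposited p-values and q-values and their up or down calls come without a stated test. Those columns were used only for the checks in the closing section. Of 34745 genes, 11414 were at 0 in all libraries. The symbols of 27 genes had been turned into dates and were restored by gene ID.

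A test on counts had been chosen before the data were examined, together with the gene lists, the naming rule and most other settings. The unit ruled it out. The test used was limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend and robust variance estimation) on log2(FPKM + 0.1), FPKM as deposited, for the 14147 genes with at least 0.5 FPKM in at least 3 libraries. Fold changes are on that scale, which understates the change of low genes. Group was the only term. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and an adjusted p under 0.05 was called. The pseudocount, filter and scaling were chosen after the unit and the values of a few genes, among them *Psenen*, *Aqp4*, *Gfap*, *Hes5*, *Hes1*, *Actb*, *Gapdh*, *Xist* and *Ddx3y*, had been seen, but before any test across genes was run, and were not changed afterwards. On simulated data for 3 control against 3 cKO libraries, with 200 of 14147 genes changed, the same steps recovered 63.2% of genes changed 1.5-fold, 82.3% of those changed 2-fold and 92.6% of those changed 4-fold, with 9 unchanged genes among 171 called. The simulated errors were independent between genes and used the fitted variances. Variation that genes share within a library was not simulated, so these shares may not hold for the real libraries.

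The 32 gene lists hold 617 entries (604 distinct genes) and cover γ-secretase and its substrates, Notch targets, the AQP4 complex, water channels, autophagy, lysosome, astrocyte, microglia, oligodendrocyte, progenitor and neuron classes, synapse, activity, vessels, meninges, choroid plexus, blood, adjoining brain regions, mitochondrial genes, stress, cholesterol synthesis and p53. A few genes stand in more than 1 list, such as *Bcas1* in both oligodendrocyte lists. Lists were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 32 lists. Camera compares a list with all other tested genes, while fry asks whether its genes move on balance one way.

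Genes were named by a rule fixed in advance. It takes the γ-secretase subunits and *Aqp4*, the 12 largest increases and 12 largest decreases among called genes with a mean of at least 1 FPKM in a group (written for CPM and applied to FPKM), libraries of the groups that do not overlap and a symbol that is not a predicted gene's, and from each list up to 4 called members by smallest p or, with none called, the 2 with the highest expression. This gave 103 genes, not all of which are named in the text. Other list members named in the text, such as *Gfap*, *S100b*, *Sox9*, *Slc1a3*, *Pdgfra*, *Map1lc3b*, *Mbp*, *Fos* and *Aqp1*, were chosen after their values were seen.

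Coordinates are those of the deposited table, on mm10 and counted from 1: 27699 gene ranges were identical to GENCODE M21 in that count. Transcript length and GC content came from the same annotation. The alternatives varied the filter, pseudocount, scaling, test options, threshold, a length and GC correction, the replicate number as a block and each library left out. Enrichment used Fisher's exact test in SciPy 1.17.1 on the KEGG and GO terms in the deposited table. Tables were handled in Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6, and figures drawn with matplotlib 3.10.9.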

Results

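Gene expression was measured by RNA sequencing of total RNA from the cerebral cortex of mice at postnatal day 8. PEN-2 is a subunit of γ-secretase, the membrane protease that cleaves Notch receptors and the amyloid precursor protein, and it is encoded by *Psenen*. The 3 control samples were Pen-2 F/F, with both alleles floxed, and the 3 Pen-2 cKO samples were Pen-2 F/F with the hGFAP-Cre transgene, which expresses Cre recombinase under a human GFAP promoter. Each sample had values for 34745 genes in FPKM, a measure of fragments scaled for gene length and sequencing depth. The smallest steps between values implied depths of 21633200, 20251900 and 24872600 fragments in control replicates 1, 2 and 3 and of 25123100, 26092700 and 26809300 in cKO replicates 1, 2 and 3. The sample titles number the samples within each group and do not state that each came from a separate animal, so the p-values measure the spread between these samples.

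The comparison asked how the cortical transcriptome differs when PEN-2 is removed with hGFAP-Cre, in a series whose title concerns astrocytic PEN-2, cerebral edema, autophagy and the water channel AQP4. The labels give the Cre transgene for the cKO samples alone, so effects of the transgene and of the deletion cannot be told apart. *Psenen* (ENSMUSG00000036835, mm10 chromosome 7, 30561868 to 30563184) was 6.35, 6.86 and 7.32 FPKM in the 3 control libraries and 3.56, 3.90 and 4.03 FPKM in the 3 cKO libraries. Its mean fell from 6.84 ± 0.485 to 3.83 ± 0.241 FPKM (SD, n = 3 per group), a log2 fold change of -0.82 (SE 0.09, limma, adjusted p = 0.00441). The gene-level values do not show which exons the remaining fragments came from. Other subunit genes did not pass the test: *Ncstn* was 17.1 ± 2.98 FPKM in control and 16.2 ± 0.300 FPKM in cKO cortex, and *Psen2*, *Aph1a*, *Aph1b* and *Aph1c* had log2 differences of -0.07, 0.03, 0.02 and 0.14.

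Across 14147 tested genes, 783 passed an adjusted p of 0.05, with 519 higher and 264 lower in cKO cortex. A change of at least 2-fold was found in 241 of them, 132 higher and 109 lower. Of the 12 largest increases, 7 were genes of the fixed lists for oligodendrocytes and their precursors, and of the 12 largest decreases, 7 were genes of the homeostatic astrocyte or Notch target lists. The share of calls that were higher, 66.3%, depended on scaling: with median-ratio scaling the calls were 314 higher and 343 lower (47.8% higher), with upper-quartile scaling 351 and 346 (50.4%), with equal sums 907 and 244 (78.8%), and after a length and GC correction 318 and 369 (46.3%). Leaving out 1 library changed the count by over 1.5 times in 4 cases: it was 311 without control replicate 1, 220 without control replicate 2, 321 without cKO replicate 1 and 312 without cKO replicate 2. Without cKO replicate 3 it was 639, with 330 higher and 309 lower (51.6% higher).

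**Figure D1:**
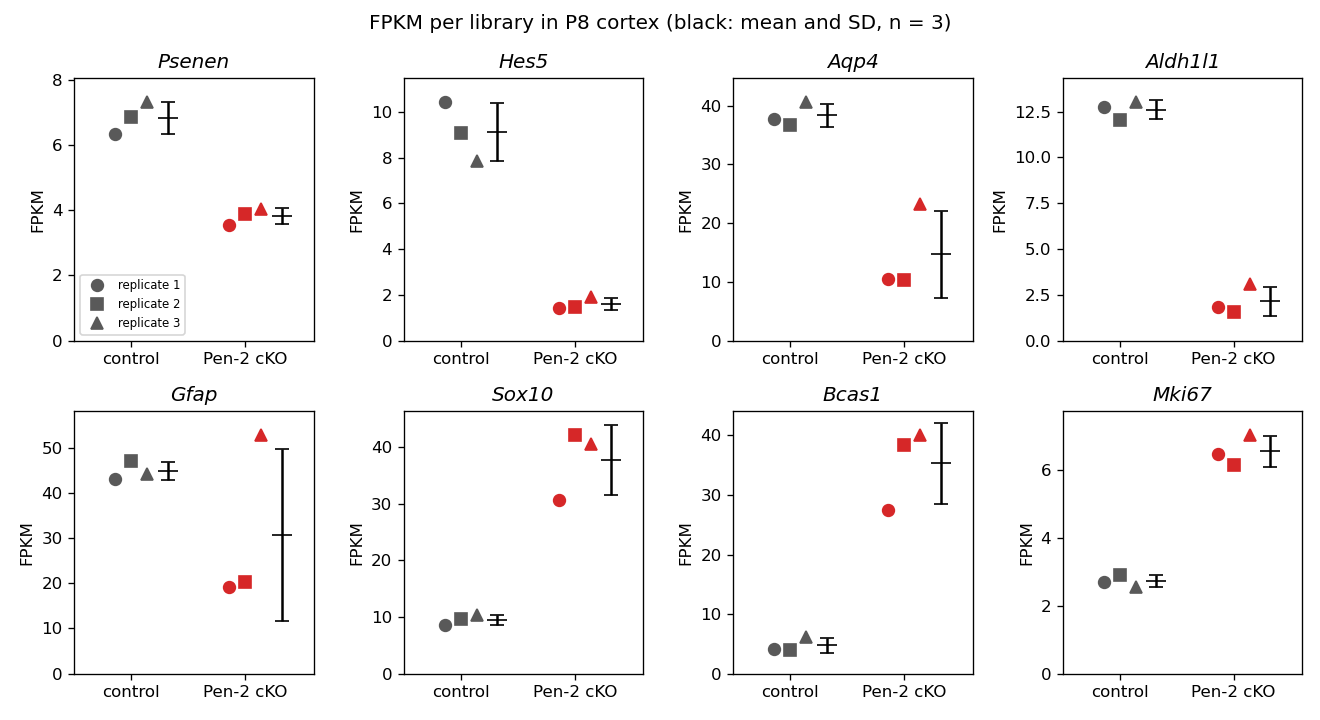
FPKM of 8 genes in each library (y axis from 0, linear; circles, squares and triangles are replicates 1, 2 and 3; black marks and bars are the mean and SD of 3 libraries). The 2 groups do not overlap for *Psenen*, *Hes5*, *Aqp4*, *Aldh1l1*, *Sox10*, *Bcas1* and *Mki67*, while *Gfap* reaches 52.8 FPKM in cKO replicate 3 and 19.1 and 20.2 FPKM in the other cKO libraries.

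Notch target genes fell. Of 14 members tested, 5 fell and none rose (7 fell when adjusted over the list alone). *Hes5*, a transcriptional repressor directly induced by Notch (ENSMUSG00000048001, chromosome 4, 154960923 to 154962371), fell from 9.13 ± 1.28 to 1.597 ± 0.269 FPKM, a log2 fold change of -2.45 (SE 0.15, adjusted p = 0.000545). *Fabp7*, a fatty acid binding protein of radial glia and young astrocytes, fell from 283 ± 1.40 to 71.8 ± 10.2 FPKM. *Nrarp*, a feedback regulator of Notch, fell from 12.2 ± 0.666 to 3.37 ± 0.524 FPKM, and *Lfng*, which glycosylates Notch, from 8.05 ± 0.600 to 3.49 ± 0.746 FPKM. *Sox9* fell with a log2 fold change of -1.50. *Hes1* was 2.03 ± 0.101 and 1.48 ± 0.226 FPKM and *Hey1* 6.52 ± 0.762 and 5.30 ± 1.05 FPKM, neither of which passed. The list as a whole lay lower than other genes (median log2 fold change -0.30, camera adjusted p = 1.27e-10), with an adjusted p = 0.135 with an estimated correlation. Radial glia and astrocytes share *Hes5* and *Fabp7*, and homeostatic astrocyte genes fell too (median log2 fold change -1.52). Bulk tissue does not separate fewer such cells from lower Notch signalling within them. Of 27 γ-secretase substrates, 3 fell (*Ptprz1*, *Notch3* and *Epha4*, log2 -0.82, -0.78 and -0.41) and 2 rose (*Nrp1* and *Dll1*, log2 0.43 and 0.57), against 1 to 4 lower and 0 or 1 higher with 1 library left out. That list did not pass (adjusted p = 0.340), and *App* was 422 ± 44.4 and 434 ± 7.98 FPKM.

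Homeostatic astrocyte genes fell, with the lowest median of the 32 fixed lists. Of 26 members, 19 fell and 1 rose (21 and 1 when adjusted over the list alone), and the median log2 fold change was -1.52 (camera adjusted p = 1.16e-27, adjusted p = 0.262 with an estimated correlation). *Aldh1l1*, a folate enzyme used as a pan-astrocyte marker (ENSMUSG00000030088, chromosome 6, 90486427 to 90600203), fell from 12.6 ± 0.517 to 2.15 ± 0.801 FPKM (log2 fold change -2.56, SE 0.22, adjusted p = 0.00158). *Aldoc*, a glycolytic enzyme, fell from 42.7 ± 3.67 to 8.05 ± 1.82 FPKM. *Slc1a3*, which encodes the glutamate transporter GLAST, fell from 33.7 ± 0.832 to 9.12 ± 3.39 FPKM, and *Glul*, which encodes glutamine synthetase, from 153 ± 12.1 to 50.2 ± 10.2 FPKM. *Ndrg2* fell from 128 ± 10.5 to 49.7 ± 4.73 FPKM, and *Slc6a11*, a GABA transporter, from 72.3 ± 3.23 to 32.7 ± 2.41 FPKM. *Slc7a10*, *Agt*, *Cldn10* and *Fgfr3* fell with log2 fold changes of -2.43, -2.39, -2.36 and -2.34. *S100b*, which mature astrocytes share with oligodendrocyte lineage cells, rose from 10.6 ± 1.53 to 20.5 ± 4.23 FPKM. *Apoe* did not pass and was 28.1, 16.4 and 85.0 FPKM in the 3 cKO libraries against 67.1, 68.7 and 73.1 FPKM in the control libraries. Without cKO replicate 3, the library with the highest *Apoe*, *Gfap* and *Ttr* values, 22 members of the list fell and 1 rose, and without each of the others 15 to 17 fell and 0 or 1 rose.

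*Aqp4* and several of its endfoot partners were lower in cKO cortex. *Aqp4* (ENSMUSG00000024411, chromosome 18, 15389394 to 15403684) was 37.8, 36.7 and 40.6 FPKM in control and 10.5, 10.4 and 23.2 FPKM in cKO libraries. Its mean fell from 38.4 ± 1.99 to 14.7 ± 7.38 FPKM, a log2 fold change of -1.49 (SE 0.31, limma, adjusted p = 0.0462). The call was close to the threshold: the adjusted p was 0.0583 with no filter on low values, 0.0607 with no mean-variance trend and 0.0534 after a length and GC correction. Leaving out 1 library gave an adjusted p of 0.107, 0.119 and 0.0880 without control replicates 1, 2 and 3, 0.143 and 0.128 without cKO replicates 1 and 2, and 0.000122 without cKO replicate 3. Among 20 tested genes of the AQP4 complex and astrocyte endfoot, 6 fell and none rose (10 fell and 1 rose when adjusted over the list alone). *Mlc1* and *Hepacam*, which encode interacting astrocyte membrane proteins, fell from 36.1 ± 9.40 to 9.64 ± 1.74 FPKM and from 18.6 ± 2.33 to 5.96 ± 2.49 FPKM. *Slc4a4*, a bicarbonate cotransporter, fell from 10.4 ± 0.236 to 3.74 ± 1.105 FPKM, and *Kcnj10*, which encodes the potassium channel Kir4.1, from 16.3 ± 2.42 to 7.49 ± 2.10 FPKM. *Dtna* fell with a log2 fold change of -0.42. The anchoring genes *Dag1* and *Dmd* had log2 differences of -0.12 and -0.10 and did not pass, nor did *Gja1* (41.2 ± 4.67 and 18.7 ± 8.69 FPKM). The list lay lower than other genes (median -0.32, camera adjusted p = 2.85e-07, adjusted p = 0.278 with an estimated correlation), and 2 to 8 of its members fell when 1 library was left out. With fry the list did not pass (adjusted p = 0.0953).

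Of 21 reactive astrocyte genes tested, 2 rose and none fell (3 when adjusted over the list alone): *Amigo2* from 3.13 ± 0.245 to 4.71 ± 0.270 FPKM, and *S1pr3*, a sphingosine phosphate receptor, from 2.02 ± 0.205 to 3.52 ± 0.509 FPKM (0 to 2 with 1 library left out, and 1 member fell without cKO replicate 3). *Gfap* did not pass (adjusted p = 0.330), at 43.1, 47.1 and 44.2 FPKM in control and 19.1, 20.2 and 52.8 FPKM in cKO libraries. *Vim* was 5.83 ± 2.60 and 7.04 ± 1.97 FPKM and *Serpina3n* 2.05 ± 0.122 and 2.74 ± 1.68 FPKM. The list had a median of 0.33 and a camera adjusted p of 0.0496 (adjusted p = 0.605 with an estimated correlation). Its call ended without cKO replicate 3 (adjusted p = 0.786), without control replicates 1 and 2 (0.170 and 0.0951), with equal sums (0.130) and with a filter at 1 FPKM (0.0560).

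Genes of the oligodendrocyte lineage rose. Of 16 precursor genes, 12 rose and none fell (14 rose and 1 fell when adjusted over the list alone), with a median of 1.197 (camera adjusted p = 9.30e-14, adjusted p = 0.262 with an estimated correlation). *Sox10*, a transcription factor required for oligodendrocyte maturation (ENSMUSG00000033006, chromosome 15, 79154913 to 79164490), rose from 9.53 ± 0.908 to 37.8 ± 6.19 FPKM (log2 fold change 1.97, SE 0.13, adjusted p = 0.000545). *Olig2* rose from 14.1 ± 1.42 to 41.9 ± 4.62 FPKM, and *Gpr17*, a receptor of committed precursors, from 21.2 ± 1.97 to 76.4 ± 10.96 FPKM. *Nkx2-2*, a transcription factor of differentiating precursors, rose from 1.12 ± 0.133 to 6.23 ± 0.731 FPKM. *Pdgfra*, the growth factor receptor of early precursors, did not pass, at 10.7 ± 0.266 and 12.9 ± 1.13 FPKM, nor did *Cspg4*, at 3.30 ± 0.464 and 4.79 ± 0.479 FPKM.

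Of 17 myelinating oligodendrocyte genes, 13 rose and none fell (14 rose when adjusted over the list alone), with a median of 1.78 (camera adjusted p = 1.32e-13, adjusted p = 0.278 with an estimated correlation). *Bcas1*, which marks newly forming oligodendrocytes (ENSMUSG00000013523, chromosome 2, 170346991 to 170427845), rose from 4.75 ± 1.28 to 35.3 ± 6.81 FPKM. *Enpp6* rose from 0.872 ± 0.317 to 7.47 ± 1.41 FPKM, and *Myrf*, the regulator of myelin gene transcription, from 0.605 ± 0.0770 to 3.92 ± 1.19 FPKM. *Fa2h* rose from 0.396 ± 0.0905 to 2.60 ± 0.501 FPKM. The compact myelin gene *Mbp* rose with a log2 fold change of 1.75. *Mag*, *Cldn11*, *Plxnb3*, *Bmp4*, *Lims2* and *Bfsp2* were also among the 12 largest increases, at log2 2.44, 2.92, 3.09, 2.71, 2.47 and 3.03. The range of *Lims2* (chromosome 18, 31931507 to 31958619) contains that of *Gpr17* (31942997 to 31949636), which also rose. Fragments of *Gpr17* can be assigned to *Lims2*, so its rise may not be a separate change. *Mog*, *Mobp* and *Mal* did not pass, with log2 differences of 1.63, 0.94 and -0.03. Beside these lists, genes of the striatum, which adjoins the cortex across white matter, had a median of 0.59, with 2 of 13 higher (*Rgs9* and *Tac1*, log2 0.59 and 0.66), against 0 to 2 with 1 library left out. The camera adjusted p of the striatum list was 0.0237 (adjusted p = 0.580 with an estimated correlation), and *Drd1* was 9.27 ± 2.16 and 10.1 ± 0.167 FPKM. The striatum call ended without control replicate 1 (adjusted p = 0.227) and without cKO replicate 3 (adjusted p = 0.110).

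**Figure D2:**
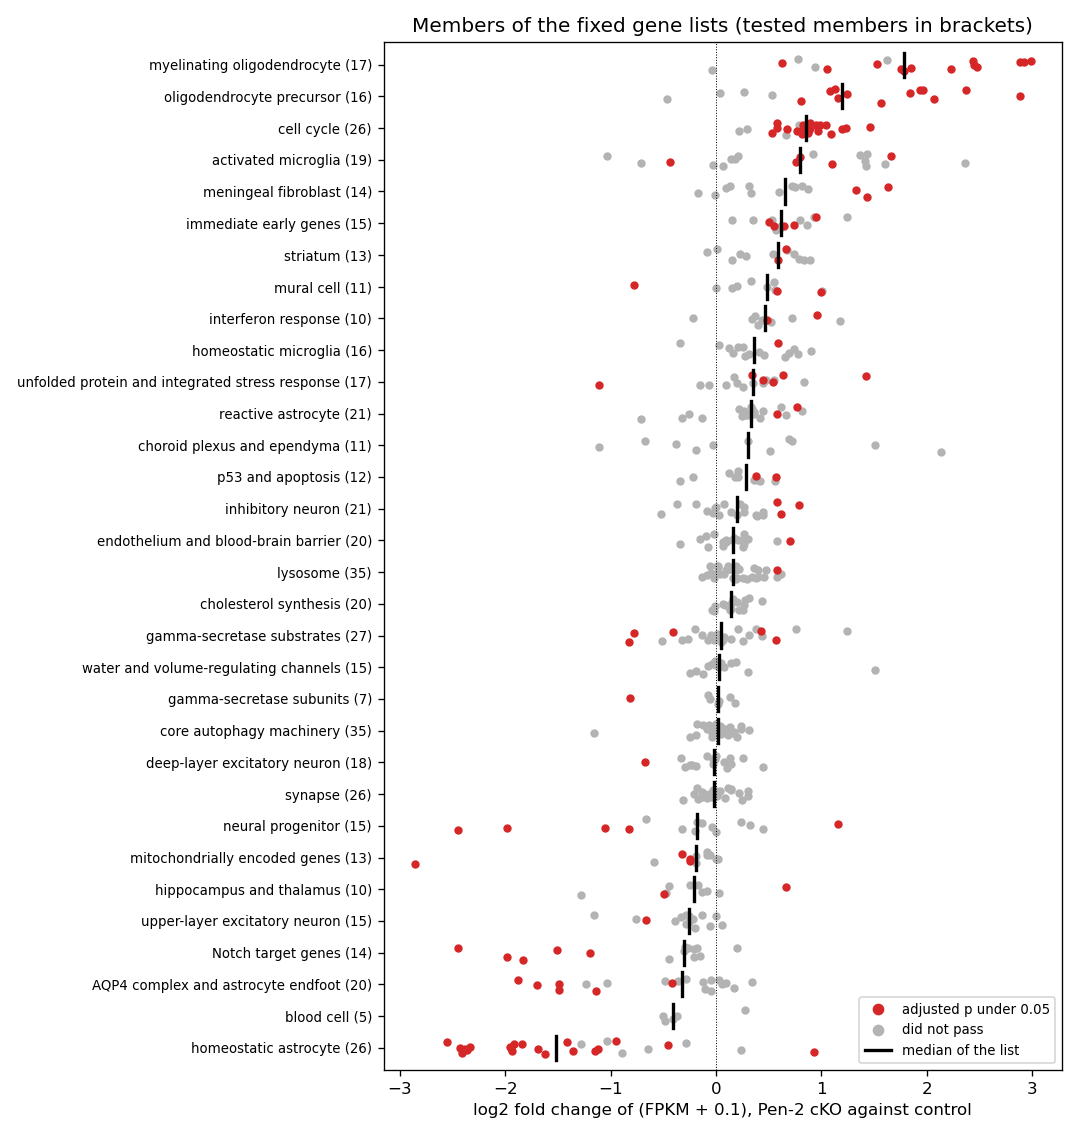
Log2 fold change of (FPKM + 0.1), Pen-2 cKO against control, for each tested member of the 32 fixed lists (x axis; 1 point per gene, red where the adjusted p was under 0.05 and grey elsewhere; black bars are list medians; lists are ordered by median and points are spread vertically for legibility). The medians run from -1.52 for homeostatic astrocyte genes to 1.78 for myelinating oligodendrocyte genes, and those of core autophagy and γ-secretase subunit genes lie at 0.02.

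Proliferation genes rose together. Of 26 cell cycle genes, 22 rose and none fell (25 rose when adjusted over the list alone), with a median of 0.86 (camera adjusted p = 2.70e-18, adjusted p = 0.105 with an estimated correlation). *Mki67* rose from 2.73 ± 0.177 to 6.55 ± 0.446 FPKM, *Top2a* from 2.40 ± 0.195 to 5.64 ± 0.566 FPKM, *Kif11* from 2.44 ± 0.253 to 5.14 ± 0.168 FPKM and *Ube2c* from 1.96 ± 0.228 to 5.58 ± 0.693 FPKM. Between 9 and 18 members rose when 1 library was left out. Neural progenitor genes moved both ways, with 4 lower and 1 higher of 15 (5 and 2 when adjusted over the list alone). *Hes5*, *Fabp7*, *Tnc* and *Ptprz1*, which radial glia and astrocytes share, fell, the latter pair by 1.05 and 0.82 on the log2 scale. The list lay lower than other genes (median -0.18, camera adjusted p = 0.000543, adjusted p = 0.278 with an estimated correlation). *Sox2* was 15.9 ± 0.140 and 19.3 ± 5.47 FPKM and *Nes* 1.92 ± 0.139 and 2.65 ± 0.1004 FPKM, neither of which passed.

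Microglial and interferon genes were higher in part. Of 19 activated microglia genes, 4 rose and 1 fell (9 and 2 when adjusted over the list alone). *Cd9* rose from 22.7 ± 0.424 to 38.7 ± 5.36 FPKM, *Tyrobp*, a microglial signalling adaptor, from 17.7 ± 1.56 to 31.2 ± 6.04 FPKM, *Cd68*, a phagocyte lysosomal protein, from 3.93 ± 0.792 to 8.74 ± 2.89 FPKM, and *Ccl4* from 0.173 ± 0.118 to 0.717 ± 0.134 FPKM. *Fabp5*, which is not restricted to microglia, fell by 0.43 on the log2 scale. Bulk tissue does not show which cells the fragments of the members that rose, such as *Cd9*, came from. With 1 library left out, 1 to 5 members rose and 1 to 3 fell. The list had a median of 0.80 (camera adjusted p = 0.0337, adjusted p = 0.545 with an estimated correlation). Its camera call ended without control replicate 1 (adjusted p = 0.184), with a filter at 1 FPKM (0.217) and with equal sums (0.0733). Of 16 homeostatic microglia genes, *Fcrls* alone rose, from 7.78 ± 0.964 to 11.7 ± 0.998 FPKM (median of the list 0.36, camera adjusted p = 0.0155, adjusted p = 0.580 with an estimated correlation). Of 10 interferon response genes, *Ifit2* and *Ifitm3* rose, by 0.48 and 0.96 on the log2 scale (median 0.46, camera adjusted p = 0.00872, adjusted p = 0.278 with an estimated correlation). Adjusted over the list alone, 4 genes of each of these latter lists rose, while with 1 library left out 0 or 1 homeostatic microglia genes and 0 to 3 interferon response genes rose.

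Vascular and meningeal genes were measured as markers of other cell types in the tissue. In the endothelial and blood-brain barrier list 1 of 20 rose, *Cdh5*, from 3.76 ± 0.561 to 6.19 ± 1.05 FPKM, and the list did not pass (adjusted p = 0.333). *Cldn5*, a tight junction gene, was 32.9 ± 3.61 and 39.8 ± 1.31 FPKM. Of 11 mural cell genes, *Tagln* and *Abcc9* rose (log2 0.99 and 0.58) and *Notch3* fell, against 0 to 2 higher and 0 or 1 lower with 1 library left out (median 0.49, camera adjusted p = 0.0337, adjusted p = 0.359 with an estimated correlation). Of 14 meningeal fibroblast genes, 3 matrix genes rose: *Dcn* from 12.7 ± 1.34 to 41.1 ± 14.2 FPKM, *Lum* from 2.59 ± 0.191 to 7.26 ± 1.61 FPKM and *Col3a1* from 2.11 ± 0.131 to 5.65 ± 1.88 FPKM (1 to 3 with 1 library left out). The meningeal list had a median of 0.66 (camera adjusted p = 0.0155, adjusted p = 0.580 with an estimated correlation), and its call ended without cKO replicate 3 (adjusted p = 0.382) and without control replicate 1 (adjusted p = 0.0503). None of 11 choroid plexus and ependyma genes passed (1 rose when adjusted over the list alone), but the choroid gene *Ttr* varied widely, at 33.1, 103.5 and 178.1 FPKM in control and 323.8, 181.8 and 876.5 FPKM in cKO libraries. None of 5 blood cell genes passed, with *Hbb-bs* at 78.1 ± 27.8 and 58.6 ± 11.9 FPKM. The blood list lay lower than other genes (median -0.41, camera adjusted p = 0.0307, adjusted p = 0.545 with an estimated correlation).

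Among neuronal genes, few passed the test. None of 26 synapse genes passed, with *Slc17a7*, the vesicular glutamate transporter of excitatory neurons, at 209 ± 36.7 and 204 ± 25.9 FPKM and *Vamp2* at 169 ± 18.3 and 169 ± 1.52 FPKM (list adjusted p = 0.307). With 1 library left out, 2 synapse genes rose without control replicate 3 and 1 without cKO replicate 3. The synapse list passed in 1 of 17 other settings. Of 15 upper-layer excitatory genes 1 fell, *Pou3f2*, from 8.48 ± 0.730 to 5.34 ± 0.877 FPKM (4 when adjusted over the list alone). That list lay lower than other genes (median -0.26, camera adjusted p = 1.25e-06, adjusted p = 0.278 with an estimated correlation). Of 18 deep-layer genes 1 fell, *Cplx3*, from 9.74 ± 0.747 to 6.11 ± 0.963 FPKM (list median -0.02, camera adjusted p = 0.0496, adjusted p = 0.421 with an estimated correlation). *Tbr1* was 15.3 ± 0.672 and 15.4 ± 1.75 FPKM. Of 21 inhibitory neuron genes, 3 rose (6 when adjusted over the list alone): *Sst*, the neuropeptide of an interneuron class, from 402 ± 36.4 to 617 ± 48.8 FPKM, *Gad1* from 14.6 ± 0.745 to 22.1 ± 3.05 FPKM and *Sox6*, which oligodendrocyte precursors also express, from 1.52 ± 0.0725 to 2.72 ± 0.495 FPKM. Between 1 and 3 rose with 1 library left out, and *Sox6* passed in 10 of 17 other settings. The inhibitory list did not pass (adjusted p = 0.134). Of 10 hippocampus and thalamus genes, *Calb1* rose by 0.67 on the log2 scale and *Rora* fell by 0.49, though no member fell with any 1 library left out (list median -0.21, camera adjusted p = 0.00188, adjusted p = 0.251 with an estimated correlation).

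Immediate early genes, which neurons transcribe within minutes of activity, were higher. Of 15, 5 rose and none fell (13 rose when adjusted over the list alone), with a median of 0.62 (camera adjusted p = 3.62e-07, adjusted p = 0.262 with an estimated correlation). *Npas4* rose from 2.73 ± 0.148 to 5.37 ± 0.396 FPKM, *Junb* from 7.52 ± 1.46 to 12.5 ± 0.489 FPKM, *Nr4a1* from 11.3 ± 0.948 to 16.6 ± 0.219 FPKM and *Btg2* from 3.10 ± 0.135 to 4.91 ± 0.209 FPKM. Between 2 and 10 members rose when 1 library was left out. *Fos* was 1.35 ± 0.497 and 3.33 ± 1.28 FPKM and did not pass.

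No transcript of the core autophagy machinery passed the test. All 35 listed genes were tested with limma, 0 passed over all genes or over the list alone, and the list did not pass camera (median 0.02, adjusted p = 0.518). *Map1lc3a* and *Gabarapl1*, members of the LC3 and GABARAP families that decorate autophagosomes, were 91.3 ± 2.06 and 88.7 ± 5.58 FPKM and 110 ± 11.4 and 118 ± 1.05 FPKM. *Sqstm1*, an autophagy receptor, was 39.7 ± 1.49 and 40.1 ± 2.02 FPKM. *Map1lc3b* was 14.5, 15.8 and 4.92 FPKM in control and 4.59, 4.68 and 4.60 FPKM in cKO libraries, and 1 gene of the list fell when control replicate 3 was left out. Of 35 lysosome genes 1 rose, *Lipa*, the acid lipase, from 5.004 ± 0.363 to 7.55 ± 1.096 FPKM (0 when adjusted over the list alone). The lysosome list had a median of 0.16 (camera adjusted p = 0.0463, adjusted p = 0.638 with an estimated correlation). None of 15 water and volume-regulating channel genes passed (1 rose when adjusted over the list alone, list adjusted p = 0.713). *Aqp1*, a water channel of the choroid plexus, was 1.29 ± 0.326 and 4.10 ± 2.00 FPKM (adjusted p = 0.0502), and *Lrrc8b* and *Slc4a10* had log2 differences of -0.07 and -0.04.

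Stress genes were higher in part. Of 17 genes of the unfolded protein and integrated stress responses, 5 rose and 1 fell (9 and 1 when adjusted over the list alone). *Ddit4* rose from 39.9 ± 2.69 to 58.0 ± 5.01 FPKM, *Sesn2* from 4.08 ± 0.182 to 6.45 ± 0.907 FPKM and *Shmt2* from 11.8 ± 0.684 to 16.2 ± 1.37 FPKM. *Phgdh*, the serine synthesis enzyme that astrocytes express strongly, fell from 20.97 ± 1.70 to 9.67 ± 1.15 FPKM. With 1 library left out, 0 to 6 of them rose and 1 fell. The list had a median of 0.35 (camera adjusted p = 0.00872, adjusted p = 0.278 with an estimated correlation). Of 12 p53 and apoptosis genes, *Cdkn1a*, a cyclin-dependent kinase inhibitor, and *Ccng1* rose by 0.57 and 0.38 on the log2 scale, though *Ccng1* passed in only 4 of 17 other settings (median 0.28, camera adjusted p = 0.0496, adjusted p = 0.278 with an estimated correlation). None of 20 cholesterol synthesis genes passed, though 3 rose when cKO replicate 3 was left out. *Hmgcs1* was 333 ± 4.64 and 332 ± 35.3 FPKM and *Fdft1* 56.7 ± 1.30 and 60.6 ± 6.84 FPKM. The cholesterol list had a median of 0.14 (camera adjusted p = 0.0463, adjusted p = 0.638 with an estimated correlation).

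Mitochondrially encoded genes were lower. Of 13, 4 fell and none rose (6 fell when adjusted over the list alone), with a median of -0.19 (camera adjusted p = 1.61e-07, adjusted p = 0.278 with an estimated correlation). *mt-Atp6* (mitochondrial genome, 7927 to 8607) fell from 9033 ± 482 to 1243 ± 17.3 FPKM, the largest decrease among the genes that the naming rule took, at log2 -2.86 (SE 0.05, adjusted p = 6.38e-07). It shares positions 7927 to 7969 with *mt-Atp8* (7766 to 7969), where fragments of either gene can be assigned to the other. A transfer of fragments to *mt-Atp8* would have raised that gene, but *mt-Atp8* fell by 0.25 on the log2 scale. This argues against a transfer to *mt-Atp8* as the cause of the fall. It does not bear on fragments that were dropped or assigned to other places, which gene-level values do not show. The cause of the fall of *mt-Atp6* therefore stays open. *mt-Nd5* and *mt-Nd1* fell by 0.32 and 0.25. Leaving out 1 library, 1 to 3 members fell, and *mt-Nd1* and *mt-Atp8* passed in 6 and 7 of 17 other settings. Mitochondrially encoded genes took 24.2% to 26.0% of the summed FPKM in control and 21.2% to 21.3% in cKO libraries. Without *mt-Atp6* these shares were 21.2% to 22.7% and 20.7% to 20.9%.

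Of the remaining largest changes, *Slc14a1*, a urea transporter, fell from 2.56 ± 0.225 to 0.349 ± 0.288 FPKM, *Folh1* from 1.59 ± 0.126 to 0.166 ± 0.0443 FPKM, *Ppp1r3g* from 1.03 ± 0.258 to 0.0906 ± 0.0293 FPKM and *Kcne1l* from 9.93 ± 1.38 to 1.82 ± 0.676 FPKM. *Prm1*, a sperm protamine gene (chromosome 16, 10796326 to 10796886), was listed at 0 in all 3 control libraries and at 6.36, 5.47 and 7.63 FPKM in the cKO libraries (adjusted p = 2.15e-05). Gene-level values do not show whether those fragments came from the gene itself or from a transgene that carries part of its sequence. Across the lists, camera with its preset correlation passed 24 of 32, fry passed 13 and camera with an estimated correlation passed 0. Fry passed the lists for Notch targets, homeostatic astrocytes, oligodendrocyte precursors, myelinating oligodendrocytes, neural progenitors, cell cycle and immediate early genes. It also passed those for interferon, mural cells, hippocampus and thalamus, mitochondrial genes, stress responses and p53. The other lists that camera passed did not pass fry, such as activated microglia and upper-layer neurons (adjusted p = 0.0650 and 0.0950). For the γ-secretase subunits, γ-secretase substrates, water channels, core autophagy and synapse lists, which did not pass, the sign of the median, the mean and the tests differed.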

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

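The checks and the weighing of explanations in this part were chosen after the results they bear on had been seen. Some list tests quoted here had been planned. These are camera on the fixed lists, at the preset and the estimated correlation, and the fits with a library left out. Their use to weigh explanations was chosen afterwards.

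The authors' deposited group values, which the comparisons above do not use, carry a signal that the 3 deposited cKO libraries do not. Of 14147 tested genes, the deposited cKO group FPKM lay above all 3 cKO libraries in 2708 and below all 3 in 1880, against 606 and 560 for the control group value and the control libraries. For *Psenen* the authors' deposited cKO value was 4.70 FPKM, above the highest cKO library (4.03 FPKM). For *Aqp4* it was 30.7 FPKM against a highest library of 23.2, and for *Gfap* 95.1 FPKM against a highest library of 52.8.

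One reading is that the group values average 4 libraries per group, 1 of which in each group is not analysed here. Multiplying each group value by 4 and subtracting the 3 libraries gave no value below 0 beyond rounding for any of 22832 genes in either group. The remainders summed to 290958 FPKM for control and 304105 FPKM for cKO, against 276530 to 294693 FPKM in the 6 libraries. A pooled-variance comparison of 4 control values, 1 of them the remainder, with the 3 cKO libraries equalled the deposited p-value within 1% for 100% of 22680 genes, while 3 control against 3 cKO libraries did so for 1.6% and 4 against 4 for 1.18%. What was averaged is not stated in the sources used here, and the remainders are algebra on deposited columns, so they entered no test. The averages would need 1 more cKO value of 78.9 FPKM for *Aqp4*, 288 FPKM for *Gfap*, 8592 FPKM for *mt-Atp6* and 7.31 FPKM for *Psenen*, where the 3 control libraries average 6.84 FPKM, so that value would show no loss of *Psenen*. The control value needed for *Psenen* also departs from its group, at 4.95 FPKM. It lies below the 3 control libraries (6.35 to 7.32 FPKM) and above the 3 cKO libraries (3.56 to 4.03 FPKM). For other genes the cKO value needed is on the side of the cKO libraries: 2.84 FPKM for *Hes5*, 5.32 for *Aldh1l1*, 46.7 for *Sox10*, 11.9 for *Mki67* and 15.3 for *Prm1*, where the control libraries average 9.13, 12.6, 9.53, 2.73 and 0 FPKM. Across tested genes the cKO remainders correlate at 0.938 on average with the cKO and at 0.915 with the control libraries. The control remainders correlate at 0.982 with the control and at 0.975 with the cKO libraries. For the 6 libraries the averages were 0.9794 to 0.9844 with their own group and 0.9677 to 0.9738 with the other. The cKO remainders thus lay further from both groups than the libraries of the 2 groups lay from each other. The authors' deposited table gives *Aqp4* a p-value of 0.0015, a q-value of 0.813 and no call, and *Psenen* a q-value of 0.592 and no call. The same table calls 593 genes up and 112 down. Of the 391 and 91 of these that were tested here, 203 and 73 were also called here in that direction and 0 in the opposite one. No biological explanation was tested for this pattern.

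The fall of the homeostatic astrocyte list was weighed against scaling and against an even loss of astrocytes. Scaling as the whole cause is argued against. It moves all genes by about the same amount, and the median log2 fold change of all tested genes was 0.0662. After median-ratio scaling the list's median was -1.58 with its call kept at the preset correlation, a shift that follows from the scaling alone. With camera at an estimated correlation the list is not called (adjusted p = 0.262, before scaling). An even loss of astrocytes, with no change in the cells that remain, would lower all genes expressed by astrocytes alone by one factor. After each library was centred on the median deviation of the members from their means, 18 of 26 members had control and cKO values that did not overlap, where chance gives 2.6. Of these, 9 fell more than the list did, such as *Aldh1l1*, and 9 fell less or rose, such as *S100b*. *Aqp4* per *Aldh1l1* was 2.96, 3.06 and 3.12 in control and 5.80, 6.60 and 7.58 in cKO libraries (*Gfap* per *Aldh1l1*: 3.38, 3.92 and 3.40, and 10.6, 12.9 and 17.2). *Aldh1l1* fell the most of the 26 members (log2 -2.56), so a ratio to it rises for any gene that fell less. The log2 fold change of *Aqp4*, -1.49, was near the list's median of -1.52, so these ratios do not show higher expression per astrocyte. Members that fell less may also be expressed by other cells, which bulk tissue does not separate, so fewer astrocytes and lower expression per astrocyte, both open as effects of the genotype, cannot be told apart.

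The rise of the oligodendrocyte lineage lists was weighed against length and GC bias and against the tissue sampled. After a length and GC correction the precursor list's median was 1.12 with its call kept at the preset correlation, which argues against such bias as the whole cause (with an estimated correlation the list is not called, adjusted p = 0.262, before the correction). More white matter or subcortical tissue in the cKO samples stays open: the striatum list, a marker of adjoining tissue, had a median of 0.5863 in the direction that this would give, though its call ended without control replicate 1 (median 0.35, adjusted p = 0.227) or cKO replicate 3 (0.45, 0.110), and the hippocampus and thalamus list lay lower (median -0.21, adjusted p = 0.00188). With an estimated correlation neither list is called (adjusted p = 0.580 and 0.251). The striatum list's most abundant genes *Penk* and *Ppp1r1b* were 30.6 ± 9.42 and 52.1 ± 13.6 FPKM and 30.9 ± 11.7 and 34.9 ± 9.69 FPKM, and the choroid gene *Ttr* was highest in cKO replicate 3. No list marks white matter apart from the oligodendrocyte genes themselves, so the tissue sampled and an effect of the genotype on the lineage cannot be told apart.

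The 783 calls were set against the other ways of splitting the 6 libraries into 3 and 3. The real split was the 1 split of 10 with that many calls, and the highest of the others had 2. With 10 splits no share under 0.05 can be reached.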

How the results depend on the processing

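The settings that replaced the planned count tools (scaling, pseudocounts, FPKM of at least 1, robust=FALSE, no trend, length and GC correction, the test against a fold) were chosen after seeing the data. Planned settings for counts (other scaling factors, other count tests) and input from the per-library tables were not run, since the files hold FPKM and the tables are identical. None of the 783 calls changed sign in any setting. *Psenen* passed in all settings run, at log2 -0.89 to -0.70. *Aqp4* kept its direction but did not pass with no filter (log2 -1.49, adjusted p = 0.0583), no mean-variance trend (-1.49, 0.0607), length and GC correction (-1.54, 0.0534), a threshold of 0.01 (-1.49) or a test against a fold of 1.2 (-1.49, 0.142). With 1 library left out it was -1.87 to -1.29, passing only without cKO replicate 3 (adjusted p 0.000122 to 0.143), while the other settings that kept it gave adjusted p of 0.0337 to 0.0475.

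The 783 calls (519 higher, 264 lower) became 499 with no filter (323 higher), where more genes share the adjustment. Thresholds of 0.01 and 0.10 gave 205 (115 higher, 90 lower) and 1519 (1070, 449), and a test against a fold of 1.2 gave 213 (124, 89). The calls that were higher numbered 314 with median-ratio scaling, 907 with equal sums and 318 after length and GC correction. The cause was not tested. With 1 library left out the calls were 220 to 842, the higher ones 135 to 582 and the lower ones 85 to 309, the lowest without control replicate 2. Fewer libraries leave less power, but the 842 calls without control replicate 3 exceed the 783 with all libraries. Power alone therefore does not account for the range, and its cause was not tested. Lists past the threshold numbered 24, 0 with an estimated correlation, 13 with fry and 14 to 24 with 1 library left out. Of the 24, 12 passed in all 17 alternatives of the camera test and 12 did not in 1 or more. Lysosome passed in 10, reactive astrocyte in 12, homeostatic microglia in 15, activated microglia in 14, deep-layer in 6, mural in 13, meningeal in 15, blood in 11, striatum in 15, stress response in 16, cholesterol in 7 and p53 in 9. No called gene and no list that passed in both settings changed direction, but 10 named genes that were not called had folds of either sign across the settings. With 1 library left out, *Pou3f2*, *Cplx3*, *Lipa* and *Cdh5*, each the 1 called gene of its list, stayed called in only 1 of 6 cases each. The deep-layer list's median ran from -0.093 to 0.032. For single named genes other than *Psenen* and *Aqp4*, 1716 of the values in other settings kept their side of the threshold and 302 did not pass where the gene had passed.

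With the replicate number as a replicate block there were 456 calls (290 higher, 166 lower), 408 of them shared with the 783. The deviations of same-numbered libraries correlated at 0.061, 0.012 and 0.1, and 4 of 6 libraries correlated best with their own number. These values do not rule out pairs. The labels state no pairing, so the main fit left the number out. Control and cKO libraries separated on the first principal component (45.1% of variance), and control replicate 3 and cKO replicate 3 stood apart on the second (19.4%), both on the same side (-17.61 and -22.97). At 20251900 to 26809300 fragments, values under 0.5 FPKM rest on few fragments. Genes with fewer than 3 libraries at 0.5 FPKM were not tested, but genes that low in 1 group alone were, such as *Prm1*, *Ccl4*, *Fa2h*, *Folh1* and *Ppp1r3g*.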

Other observations

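The enrichment tests in this part were chosen after seeing the data, and the genes named from them after their values were seen. Of 300 KEGG pathways tested, 5 passed for lower genes: PPAR signalling (9 genes, 1.15 expected, Fisher's exact test, adjusted p = 0.000443), nitrogen metabolism (4, 0.25 expected), arginine biosynthesis (4, 0.33 expected), biosynthesis of unsaturated fatty acids (5, 0.65 expected) and arachidonic acid metabolism (5, 0.73 expected). The fatty acid metabolism pathway did not pass (6, 1.3 expected, adjusted p = 0.087). *Scd1* and *Scd2*, which desaturate fatty acids, fell from 26.7 ± 3.36 to 9.09 ± 0.529 FPKM and from 251.8 ± 15.7 to 179 ± 2.47 FPKM. *Fads2* fell from 142 ± 4.20 to 84.6 ± 2.93 FPKM. *Dbi*, an acyl-CoA binding protein, fell from 38.7 ± 2.58 to 19.1 ± 2.37 FPKM, *Glud1*, glutamate dehydrogenase, from 73.1 ± 3.03 to 35.5 ± 3.60 FPKM, and *Car2*, a carbonic anhydrase, from 14.6 ± 1.26 to 4.64 ± 0.358 FPKM. *Fabp7*, *Acsbg1* and *Glul* in these pathways also stand in the astrocyte or Notch lists.

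For higher genes 6 pathways passed: cell cycle (21 genes, 4.83 expected, adjusted p = 2.17e-06), DNA replication (9, 1.44 expected), protein digestion and absorption (10, 1.96 expected), p53 signalling (11, 2.70 expected), HIF-1 signalling (12, 3.74 expected, adjusted p = 0.0180) and biosynthesis of amino acids (9, 2.57 expected). In protein digestion and absorption 7 of the 10 were collagens, among them the basement membrane genes *Col4a1* (12.2 ± 1.33 to 21.4 ± 3.003 FPKM) and *Col4a2* (10.7 ± 1.54 to 16.3 ± 1.53 FPKM). *Col3a1*, another of them, is in the meningeal fibroblast list, which also rose (median 0.66) but did not pass without cKO replicate 3 (adjusted p = 0.382), without control replicate 1 (0.0503) or with an estimated correlation (0.580). In HIF-1 signalling *Pgk1* (99.5 ± 2.97 to 123.8 ± 4.31 FPKM), *Ldha* (105 ± 4.98 to 138 ± 9.30 FPKM), *Pfkl* and *Hk2* (log2 0.57 and 1.43) rose, while the glycolysis pathway itself did not pass (6 genes, 2.04 expected, adjusted p = 0.223). *Ccnd1*, which stands in cell cycle and p53 signalling, rose from 8.23 ± 1.99 to 19.3 ± 1.13 FPKM. Among GO terms, 87 passed for higher and 50 for lower genes of 4817 tested, led by the spindle (36 genes, 9.57 expected) and by glial cell differentiation (16 genes, 3.0 expected). Many of these terms share genes, so the counts are not independent.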
